A study of Mus musculus with 2 samples.

How the data were processed

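Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters preferentially into open DNA, in hearts of newborn mice at postnatal day 0. Per the labels, the series holds 1 group of 2 libraries, each a biological replicate made from a mixed-sex pool of hearts of the strain B6NTac;B6NCrl/Lap. The pool of replicate 1 came from 15 mice, and the number of mice in the pool of replicate 2 is not stated. No other tissue, age or treatment was included, so the design allowed a description of the accessible regions and a comparison of the libraries with each other.

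Peak lists in mm10 coordinates were the data used, and the peaks and all of their values are those of the authors. For each library the authors gave a set thresholded on the irreproducible discovery rate (IDR), a more permissive pseudoreplicated set and a ranked list, and they gave further sets called from both libraries together. The readme files list an exclusion list of genome regions among the inputs of the thresholded, pseudoreplicated and replicated sets, and none among those of the ranked lists. The aligner, the peak caller and their settings are not given in the sources used here. The deposited score of a thresholded or ranked entry is a transform of its IDR: within a tolerance of 1, all scores of both ranked lists (100.0%) matched a fixed negative multiple of the log2 of the global IDR, with an upper limit of 1000, and the lowest score in each library's thresholded set corresponded to an IDR of 0.05. The deposited score of an entry in the pseudoreplicated and replicated sets is a display score made from its p value. The signal value given by the authors is an enrichment ratio of the peak over its local background, with no further scaling stated, and it was used to describe and rank peaks. The deposited columns of significance hold -log10 p and -log10 q as the peak caller gave them. The pooled ranked lists were not used, because nothing tied their columns to a library. The number of used columns that matched no sample was 0. No read counts were used here, so the sequencing depth of each library is unknown, and the number of called regions, their length and their signal were taken as the only measures of what each library could show.

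Entries on the 21 chromosomes that overlapped by 1 bp or more were merged into regions, each with the signal value and summit of its strongest entry. Regions present in both libraries' thresholded sets after joint merging were called both-library regions. All entries on each of the 21 chromosomes ended within the length of that chromosome in the GRCm38 reference, the build that corresponds to mm10, and the GENCODE annotation of that build was used, with 55413 genes, of which 21911 symbols were protein-coding. A summit was assigned to a promoter when it lay within 1 kb of the 5' end of any annotated gene, then to an exon, an intron or intergenic sequence, in this order. A region was distal when its summit lay more than 2 kb from every annotated transcript start. A gene's promoter counted as accessible when a region lay within 1 kb of its 5' end in the thresholded sets of both libraries. Positions are printed with the first base of a chromosome counted as 1.

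Overlap between the libraries was compared with 100 random placements of the same regions on the same chromosomes, outside assembly gaps of at least 1 kb, and location with 100000 random positions. Promoter accessibility of 21 gene lists with 354 members in total, all of which matched the annotation by symbol, was compared with all other protein-coding genes by Fisher's exact test, two-sided. The median number of distal both-library regions within 100 kb of a gene's 5' end was compared with 10000 random lists matched on promoter status and on 10 classes of gene length, by a two-sided permutation test whose smallest possible p is 0.0002. The lists covered cardiomyocyte genes, cardiac transcription factors, conduction and ion channel genes, fatty acid oxidation, glycolysis, cell cycle and housekeeping genes. They also covered markers of endothelial and endocardial, fibroblast, epicardial, smooth muscle and pericyte, immune, erythroid, and neural crest and Schwann cells, and of lung, thymus, neuron, liver, skeletal muscle, pluripotency and germline, and intestine and pancreas. For 21 consensus motifs, the share of distal regions holding the motif on either strand in the 200 bp around the summit was compared with the same sequences shuffled with their dinucleotide counts kept, by an exact binomial test on the pairs that differed. The share in promoter regions was compared with the distal share by Fisher's exact test. P values were adjusted by the Benjamini-Hochberg method over the 21 lists or the 21 motifs, with a threshold of 0.05. Signal in the libraries was compared as the log2 ratio of replicate 2 over replicate 1 less the median ratio of all both-library regions. This was done for the regions of each list, beside 10000 random sets matched on 10 classes of mean signal and without a p value, because each side was a single library. A region was assigned to a list when it lay within 1 kb of a member's 5' end, or was distal with a member's 5' end the nearest and within 100 kb. The 18 lists with at least 3 such regions were compared. Regions of 1 library only were those that no region of the other library's pseudoreplicated set overlapped. Genes and regions are not independent replicates, so every test describes these 2 libraries.

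The lists, motifs, tests and alternatives were fixed before the data were examined, except for 4 alternatives named as later choices in the closing section. Genes were named by a rule fixed at the same time. For each list it took the 3 members of highest promoter signal and up to 2 members, first in the alphabet, with no promoter region in the thresholded set of either library. It further took the 10 strongest distal regions with their nearest protein-coding gene, the 10 genes with the most distal regions, and the 3 strongest regions of each library that the other lacked. Any member of the cardiomyocyte and cardiac transcription factor lists could also be named for the presence or absence of a promoter region. Alternatives covered an IDR of 0.01, the permissive sets, unmerged entries, a reciprocal overlap of 0.5, and promoter windows of 500 bp and 2 kb. They also covered every annotated transcript start, gene windows of 50 kb and 200 kb, motif windows of 100 bp and 400 bp, flanking sequence 1 kb from the summit as the motif background, other matching, other centring, and leaving out each library in turn. Intervals are exact 95% binomial intervals and cover counting error only. Values given with an SD are means of the 2 libraries. Sequence matches to the mitochondrial genome were searched with blastn 2.17.0 and copies on the chromosomes with minimap2 2.31. The other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The procedures were tested on simulated data: 3% of 200 random lists passed an unadjusted p of 0.05 in the promoter test and 0% in the distal test, and 99.5% and 97.5% of 200 enriched lists of 20 genes were recovered at that p. The planted enrichment was strong. Promoter lists were set at 90% accessible in replicate 1, and distal lists drew 60% of members from genes with 2 or more distal regions. Weaker enrichment was not simulated, so these shares do not give the power for lists that did not pass. A MEF2 motif planted in 10% of sequences was found in 11.2%, and 99.5% of sets of 60 regions lowered by 0.2 on the log2 scale were found.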

Results

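The data are maps of accessible chromatin in the heart of newborn mice, from 2 ATAC-seq libraries of 1 group. Replicate 1 had 21001 accessible regions covering 14.7 Mb, with a median length of 665 bp, and replicate 2 had 25174 regions covering 18.3 Mb, with a median length of 692 bp. These were merged from 39905 and 50297 deposited entries. The median signal value, an enrichment over local background, was 9.80 in replicate 1 and 10.97 in replicate 2, and the highest values were 61.8 and 60.9. The authors' pooled thresholded set held 31846 regions. Read counts were not used here and the depth is unknown, so a region missing from a list is reported as not called and not as closed.

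How far the libraries gave the same regions was asked first. Of the regions of replicate 1, 89.7% (95% interval 89.2 to 90.1%) were overlapped by a region of replicate 2, against 1.47% for randomly placed regions. Of the regions of replicate 2, 73.9% (73.4 to 74.5%) were overlapped by a region of replicate 1, against 1.24% at random. After joint merging, 18463 regions were present in both libraries. Across these 18463 regions, log2 signal values correlated with a Spearman coefficient of 0.887 and a Pearson coefficient of 0.890, which describe regions that are not independent replicates. Signal in replicate 2 was higher by a median log2 ratio of 0.21, with an SD across regions of 0.26.

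**Figure D1:**
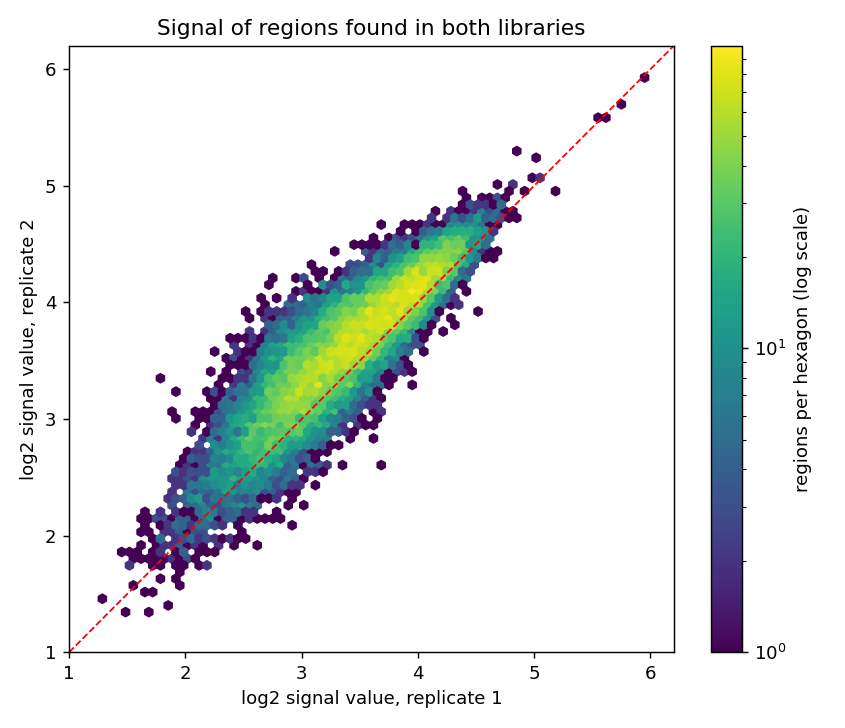
Signal value of each both-library region in replicate 1 (horizontal axis, log2) against replicate 2 (vertical axis, log2), with lighter hexagons holding more regions and a dashed line at equal values. The cloud of 18463 regions lies along the line and slightly above it, with a median log2 ratio of 0.21.

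Where the accessible regions lay was asked next. Promoters held 49.8% of the regions of replicate 1 and 44.4% of those of replicate 2, a mean of 47.1% ± 3.86 (SD, n = 2), against 3.95% of random positions. Among both-library regions, 53.7% were at promoters, 26.1% in introns, 15.2% between genes and 5.005% in exons. Distal regions, more than 2 kb from every transcript start, numbered 6281, or 34.0% of the both-library regions. Promoter regions had a median signal of 13.6 and distal regions one of 9.85. The promoter share depended on the set of peaks and was 23.2% in the authors' pooled replicated set.

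Genes of the cardiomyocyte, the contractile cell of the heart, more often had an accessible promoter than other protein-coding genes. The promoter was accessible in both libraries for 21 of 28 genes of the list, or 75% (55.1 to 89.3%), against 46.9% of other genes (odds ratio 3.40, Fisher's exact adjusted p = 0.0065). The highest promoter signals of the list were those of Myl4, an atrial myosin light chain, at 13.1 ± 2.13 (SD, n = 2), Cacna1c, the pore subunit of the L-type calcium channel, at 12.8 ± 1.34, and Myom1, a protein of the sarcomere's M-band, at 11.7 ± 0.198. Chosen after their values were seen, Ttn, the giant spring protein of the sarcomere, had 11.2 ± 1.17, and the myosin heavy chains Myh6 and Myh7 had 5.37 ± 0.364 and 4.68 ± 0.826. A signal value is a ratio over local background, so a lower one does not by itself mean a less open promoter. In the thresholded sets, no region within 1 kb of the 5' end was called in either library for Corin, Myl3, Myl7, Smyd1 and Tnni3, but the permissive sets of both libraries held one for Corin, Myl3 and Myl7. Nppa, the atrial natriuretic peptide gene, had a thresholded one in replicate 2 alone and Tnni1, the slow skeletal and fetal troponin I gene, in replicate 1 alone. When the comparison was limited to genes with a region within 100 kb, the list was 15.2 points above other genes and no longer passed (exact adjusted p = 0.155), but this filter removes almost only genes without an accessible promoter, so it raises the background by construction.

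Promoters of genes for energy metabolism, cell division and basic cell functions were also accessible more often than those of other genes. In the fatty acid oxidation list 18 of 20 promoters were accessible (exact adjusted p = 0.00058), with signals of 17.9 ± 1.51 (SD, n = 2) at Etfb and 17.3 ± 0.632 at Etfa, the subunits of the electron transfer flavoprotein, and 16.5 ± 1.57 at Pdk4, a kinase that inhibits pyruvate dehydrogenase. Cd36, a fatty acid transporter, had no region at its 5' end in either library. In the glycolysis list 14 of 16 were accessible (exact adjusted p = 0.0036), led by Pgk1 at 16.2 ± 2.08, Eno1 at 15.9 ± 0.467 and Pfkl at 15.9 ± 1.90, while Hk1 and Ldha had none at the 5' end. In the cell cycle list 20 of 21 were accessible (exact adjusted p = 5.0e-05), with 22.9 ± 2.01 at Ccna2, which encodes cyclin A2, 21.01 ± 1.93 at Pcna, the sliding clamp of DNA replication, and 18.8 ± 4.02 at Mcm5, a subunit of the replicative helicase. In the housekeeping list, which shares Gapdh and Pgk1 with the glycolysis list, 15 of 16 were accessible (exact adjusted p = 0.00058), with 18.4 ± 1.20 at Sdha, 17.6 ± 0.828 at Rplp0 and 17.4 ± 2.65 at B2m, and none at the 5' end of Ywhaz. When every annotated transcript start was used, all members of these 4 lists, Cd36, Hk1, Ldha and Ywhaz included, had an accessible start in both libraries. Against random lists matched on promoter CpG content, the cell cycle list did not pass singly (permutation adjusted p = 0.0731).

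The remaining 8 lists for the heart, its other cell types and neighbouring tissue did not pass the test. For cardiac transcription factors, 15 of 24 promoters were accessible (exact adjusted p = 0.172), with signals of 15.0 ± 0.250 (SD, n = 2) at Mef2a, 15.0 ± 0.963 at Hey2 and 14.2 ± 1.55 at Tbx20. In the thresholded sets, Hand1, Irx4, Mef2c, Nkx2-5, Pitx2, Tbx2 and Tbx5 had no promoter region in either library, and Esrrg and Isl1 had one in a single library. The permissive sets held one in both libraries for Hand1, Irx4 and Tbx2 and in replicate 1 for Pitx2 and Tbx5. This list passed when every annotated transcript start was used, 28.4 points above other genes (exact adjusted p = 0.0101), and in the permissive sets, 26.2 points above (exact adjusted p = 0.0223), while against random lists matched on promoter CpG content it stood at -13.2 points (permutation adjusted p = 0.165). Conduction and ion channel genes had 8 of 18 (exact adjusted p = 1), with 17.3 ± 3.96 at Kcnj2, the inward rectifier potassium channel, and 14.6 ± 4.81 at Gja5, which encodes connexin 40, and they passed in the permissive sets (exact adjusted p = 0.0453). Endothelial and endocardial markers had 5 of 20 (exact adjusted p = 0.0989), with 13.3 ± 1.28 at Tie1, a receptor of endothelial cells. That list stood at -38.0 points relative to other genes at an IDR of 0.01 (exact adjusted p = 0.0012), and 12.8 points above them in the permissive sets (exact adjusted p = 0.314). It also passed as lower within 500 bp (exact adjusted p = 0.0357). The same held among genes with a region within 100 kb (exact adjusted p = 0.0079), a filter that raises the background by construction. Fibroblast markers had 5 of 18 (exact adjusted p = 0.172), with 10.3 ± 0.976 at Fn1, which encodes fibronectin, and, for Col3a1, a promoter region in the permissive sets alone, and they passed as lower at an IDR of 0.01 (exact adjusted p = 0.0105). Epicardial markers had 3 of 12 (exact adjusted p = 0.172), namely Sema3d at 11.5 ± 2.30, Krt8 at 10.3 ± 1.99 and Tbx18 at 9.15 ± 0.0918. Smooth muscle and pericyte markers had 7 of 12 (exact adjusted p = 0.594), with 8.61 ± 2.29 at Acta2, the smooth muscle actin gene. Erythroid genes had 3 of 14 (exact adjusted p = 0.0959), namely Tfrc at 18.9 ± 1.02, Klf1 at 11.7 ± 2.91 and Nfe2 at 10.2 ± 0.237. They passed as lower without replicate 1 (exact adjusted p = 0.0496), within 500 bp (0.0392) and with every transcript start (0.0457). Against lists matched on promoter CpG content, the erythroid difference was 0.74 points (permutation adjusted p = 1). Lung markers had 2 of 10 (exact adjusted p = 0.152), namely Foxj1 at 14.2 ± 5.35 and Hopx at 8.20 ± 1.06, and they passed as lower in the permissive sets (exact adjusted p = 0.0376).

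Promoters of marker genes of other tissues, of immune cells and of neural crest and Schwann cells were accessible less often than those of other genes, in 8 lists. A promoter that was not called in whole hearts may still be open in a rare cell type. None of the promoters was accessible in both libraries among 20 liver genes (0 to 16.8%; exact adjusted p = 5.0e-05), among 16 immune genes (0 to 20.6%; exact adjusted p = 0.00032), among 14 intestine and pancreas genes (0 to 23.2%; exact adjusted p = 0.00058) and among 10 thymus genes (0 to 30.8%; exact adjusted p = 0.0044). They included Afp and Ahsg, which encode secreted proteins of the fetal liver, Adgre1 and C1qa of macrophages, Cdx1 and Cdx2 of the intestine, and Cd3d and Cd4 of T cells. In the neuron list 2 of 20 were accessible, Syn1 at 11.8 ± 0.605 (SD, n = 2) and Neurog2 at 9.28 ± 1.26, and in the skeletal muscle list 2 of 20, Actn3 at 19.4 ± 1.51 and Mylpf at 12.6 ± 0.723 (exact adjusted p = 0.0027 for each list). In the pluripotency and germline list 1 of 14 was accessible, Dazl at 16.4 ± 0.932 (exact adjusted p = 0.0044), and in the neural crest and Schwann list 1 of 11, Mpz, a myelin protein gene, at 16.9 ± 4.94 (exact adjusted p = 0.0216). The neuron list (exact adjusted p = 0.0890) and the neural crest and Schwann list (exact adjusted p = 0.0890) no longer passed in the permissive sets, and the latter did not pass with promoters within 2 kb (exact adjusted p = 0.101). Against random lists matched on promoter CpG content, the immune, liver and thymus lists did not pass singly (permutation adjusted p = 0.0567, 0.0641 and 0.159). With 0% accessible, the lowest share possible, none of these lists could have reached a smaller p as lower. For thymus the central range of the matched lists, 0 to 40%, itself held 0%. Not passing is therefore no evidence that CpG content accounts for these low shares.

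**Figure D2:**
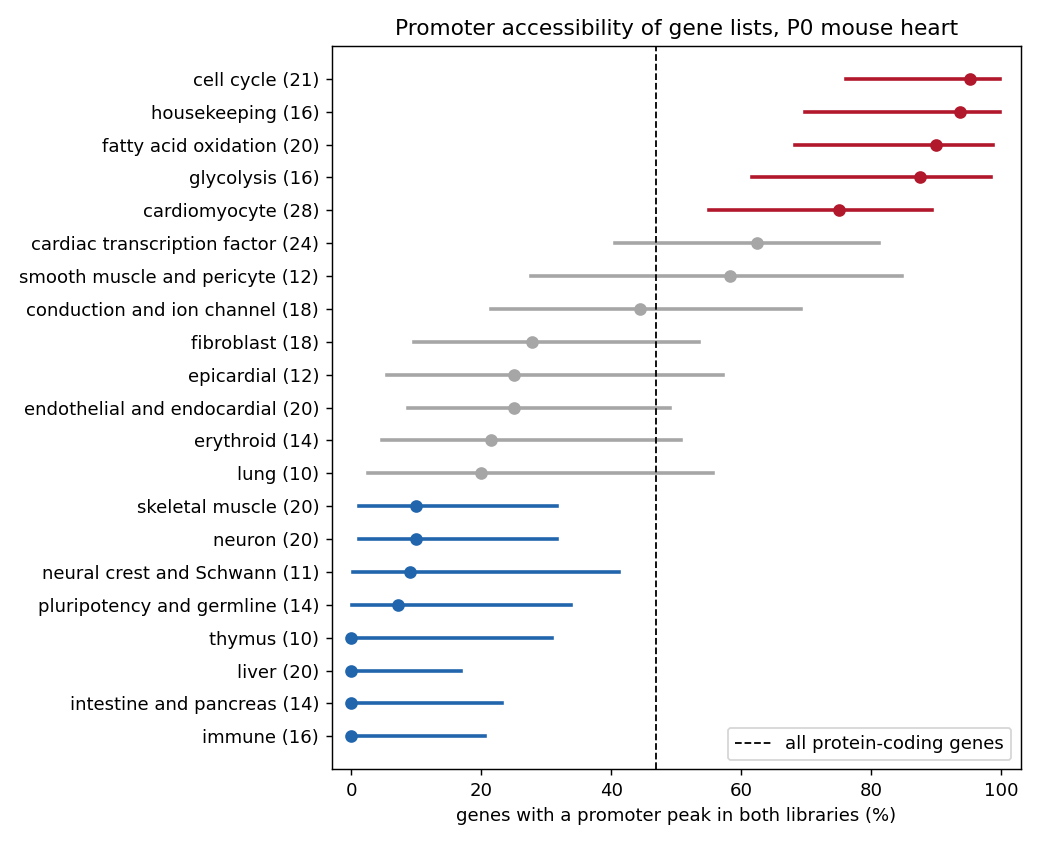
Percent of the genes of each list with an accessible promoter in both libraries, with bars for the exact 95% interval; red marks lists above and blue lists below other protein-coding genes at an adjusted p under 0.05, and grey the others. The cell cycle list had 20 of 21 accessible promoters and the liver list 0 of 20.

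Distal accessible regions gathered around cardiomyocyte genes. Genes of this list had a median of 3 distal regions within 100 kb of the 5' end, against 0 in matched random lists (permutation p = 0.0002, the smallest possible, adjusted p = 0.0042), and 27 of the 28 genes had at least 1. Among members picked after their values were seen, Nppb, the B-type natriuretic peptide gene, had 7, Actn2, which encodes a sarcomeric actinin, 6, Nppa 5 and Tnni1 4, while Myl7 had 0. Nppa and Nppb lie next to each other, so some regions were counted for both, but the list's median was also 3 above random with neighbouring members counted once, a choice made after the data were seen. Cardiac transcription factors had a median of 1.5 against 0 (permutation adjusted p = 0.0294), with 3 at Irx4 and 3 at Mef2a, and 5 at Gata4 and 3 at Nkx2-5 among members picked after their values were seen. The pluripotency and germline list also had a median of 1.5 against 0 (permutation adjusted p = 0.0294), including 2 at Ddx4, but it did not pass without replicate 2 (permutation adjusted p = 0.0808), with no matching (permutation adjusted p = 0.105) or in the permissive sets (permutation adjusted p = 0.0781). It also did not pass with neighbouring members counted once (permutation adjusted p = 0.0644) or by the mean (permutation adjusted p = 0.137), choices made after the data were seen. The other 18 lists did not pass, with adjusted permutation p values from 0.123 for fatty acid oxidation upward. Endothelial and endocardial genes, with a median of 1 against 0, passed in the 50 kb window (permutation adjusted p = 0.0182), without replicate 2 (0.0434) and in the permissive sets (0.0168), and conduction and ion channel genes passed in the 50 kb window (0.0395). By the mean, both of these lists passed, as cardiac transcription factors did (permutation adjusted p = 0.0210 for each). Fatty acid oxidation passed with no matching (permutation adjusted p = 0.0308) and lung in the permissive sets (0.0252).

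**Figure D3:**
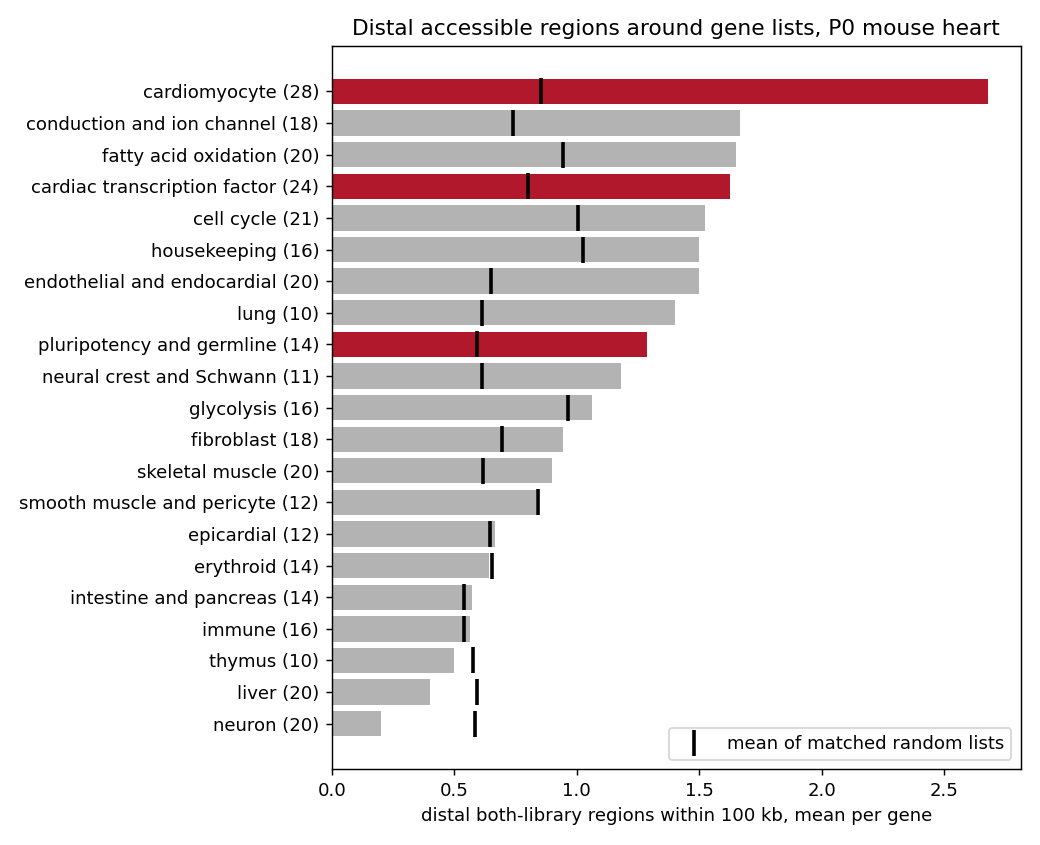
Mean number of distal both-library regions within 100 kb of the 5' end per gene for each list, with ticks for the mean of matched random lists; red bars mark lists whose median passed the permutation test. The cardiomyocyte list had a mean of 2.68 against 0.853 at random.

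Across all protein-coding genes, 12851 had no distal region within 100 kb. Irf2bpl, a gene for a nuclear protein of the interferon regulatory factor 2 binding family, had the most, with 12 such regions, and its promoter signal was 9.79 ± 1.15 (SD, n = 2). Hdac7, a class IIa histone deacetylase gene, and its neighbour Vdr, which encodes the vitamin D receptor, had 9 each, as had Irf2bp2, Tfap4, Tmem173 and Ube2d2a. A further 13 genes had 8 each, of which Abtb1, Atp23 and Avil came first in the alphabet.

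The strongest single distal region lay between genes on chromosome 2, from 69355469 to 69355735, 12.985 kb from the 5' end of Abcb11, with a signal of 61.4 ± 0.662 (SD, n = 2). The next were a region on chromosome X from 143482935 to 143483180 near Pak3, with 53.2 ± 0.708, one on chromosome 10 from 96077545 to 96077953 near Gm5426, with 49.1 ± 0.558, and one on chromosome 5 from 60042683 to 60043153, 1766 kb from G6pd2, with 47.8 ± 1.12. The remaining 6 of the 10 strongest, nearest to Hic2, Frmd4a, Cdh20, Nxph1, Myl12b and Galc, had signals from 30.6 to 35.3. Of these 10 regions, 4 matched the mitochondrial genome, those nearest to Gm5426, G6pd2, Nxph1 and Galc, against 1 of the other 6271 distal regions. Another copy on the chromosomes was found for 5 of the 10, against 1 of 200 other distal regions drawn at random. The regions near G6pd2, Nxph1 and Galc had both kinds of match.

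Of the 21 motifs, 12 were more frequent in distal regions than in shuffled sequence, among them those of MEF2, TEAD and GATA factors, and 1, that of TBX5, was less frequent, while that of NKX2-5 did not pass. The MEF2 motif, bound by factors that activate muscle genes, was present in 9.30% (8.59 to 10.04%) of the 6281 distal regions, against 0.223% of shuffled sequences (exact adjusted p = 5.5e-158) and 1.23% of promoter regions. The TEAD motif, bound by effectors of the Hippo pathway, was present in 10.2% (9.50 to 11.01%) against 2.95% (exact adjusted p = 8.6e-64), and the GATA motif in 5.33% (4.79 to 5.92%) against 1.497% (exact adjusted p = 7.6e-33). The AP-1 motif was present in 9.28% against 4.23% (exact adjusted p = 5.4e-30), and the CArG box bound by serum response factor in 1.94% against 0.621% (exact adjusted p = 7.2e-11). The ESRR motif, bound by estrogen-related receptors, was present in 1.05% against 0.255% (exact adjusted p = 4.7e-08), a difference that did not pass against flanking sequence (exact adjusted p = 0.695). The motif of CTCF, a factor that shapes chromosome loops, was present in 2.83% against 0.0159% (exact adjusted p = 3.3e-51). The E-box CAGCTG was present in 24.8% against 18.8% (exact adjusted p = 1.0e-16). The motif of NKX2-5, present in 5.78% of distal regions against 5.94% of shuffled sequences (exact adjusted p = 0.906), did not pass. It was above background by 1.02 points against flanking sequence (exact adjusted p = 0.0237) and by 0.701 points in 100 bp windows (exact adjusted p = 0.0409), and below it in 400 bp windows, at 10.5% against 12.1% (exact adjusted p = 0.0108). The TBX5 motif was less frequent in distal regions than in shuffled sequence, at 1.02% against 1.80% (exact adjusted p = 0.00046), but not in 100 bp windows (exact adjusted p = 0.381) or against flanking sequence (exact adjusted p = 0.317). With 20 shuffles, a choice made after the data were seen, the mean TBX5 background was 1.57%. The median adjusted p of the exact test was then 0.0218, and 13 of the 20 shuffles passed. Of the motifs above, the background in flanking sequence differed from the shuffled one by over 1.5 times for MEF2, at 3.08%, GATA, at 2.75%, CTCF, at 0.0799%, ESRR, at 0.927%, and the E-box CAGCTG, at 9.94%. The ratio of distal regions to background was 3.02 for MEF2 there and 41.7 with shuffling. Except for ESRR, these motifs also passed against flanking sequence.

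Some motifs were more frequent in promoter regions than in distal regions. The SP/KLF motif was present in 21.9% of promoter regions and 2.93% of distal regions (Fisher's exact adjusted p = 4.2e-294), and the NRF1 motif in 10.6% and 0.955% (exact adjusted p = 2.0e-156). Both were also above shuffled sequence in distal regions, at 0.350% (exact adjusted p = 4.5e-34) and 0.143% (exact adjusted p = 5.2e-10), with 0.575% and 0.0799% in flanking sequence. The ETS motif was present in 2.24% of promoter regions and 0.111% of distal regions (exact adjusted p = 4.2e-38). Promoter regions were richer in G and C, at a mean of 65.9% against 54.3% in the 200 bp around the summit. The OCT motif, at 0.685% against 0.303% (exact adjusted p = 0.0055), and the neuronal E-box, at 5.48% against 4.46% (exact adjusted p = 0.0152), passed, but with 20 shuffles, a choice made after the data were seen, their median adjusted p values of the exact test were 0.145 and 0.0515, and the OCT motif did not pass without replicate 1 (exact adjusted p = 0.422). OCT lay below background in 100 bp windows, at 0.287% against 0.303%, and against flanking sequence, at 0.671% against 1.04%, without passing. In 100 bp windows the neuronal E-box did not pass (exact adjusted p = 0.0524). The ETS, NFI, HNF4, HNF1, REST, SOX10-like dimer and RUNX motifs did not pass, and each was present in less than 1% of distal regions. The ETS motif passed without replicate 1 (exact adjusted p = 0.0430) and without replicate 2 (0.0176), and the RUNX motif without replicate 2 (0.0333).

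**Figure D4:**
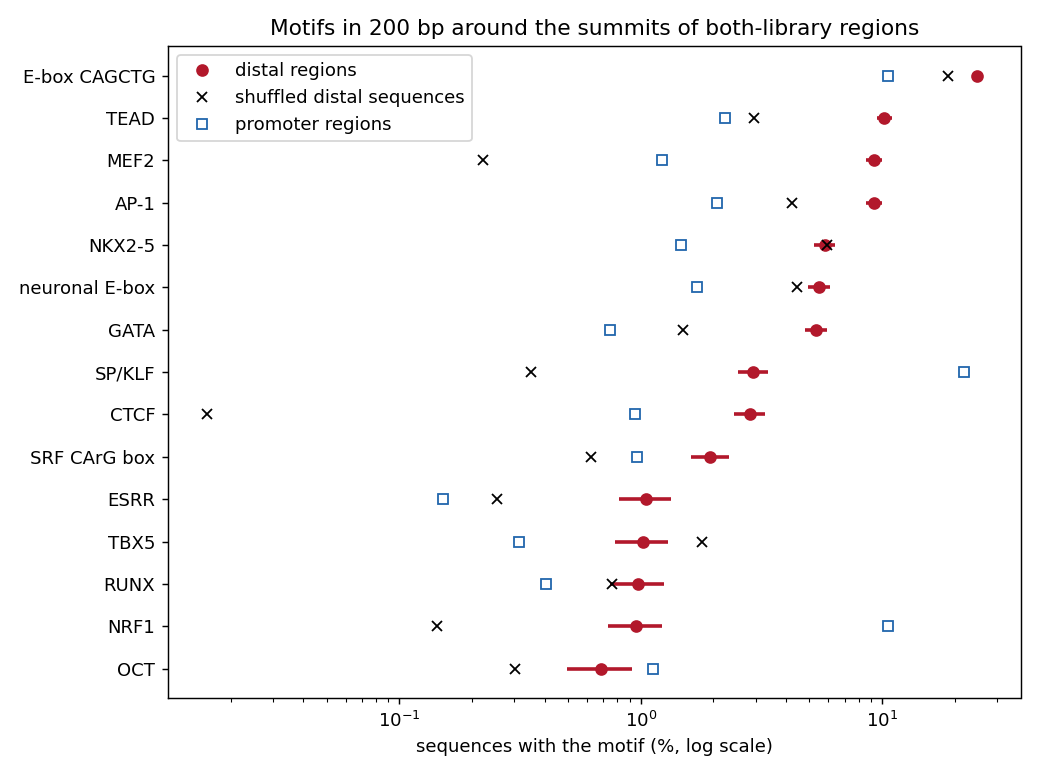
Percent of regions holding each motif present in at least 0.5% of distal regions, on a log axis, with red dots and 95% intervals for the 6281 distal regions, crosses for the same sequences shuffled and squares for promoter regions. The MEF2 motif was in 9.30% of distal regions and 0.223% of shuffled sequences.

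The libraries were compared list by list, to see whether cell types were equally represented in them. Regions of cardiomyocyte genes had relatively less signal in replicate 2, with a median log2 difference of -0.19 (SD across 63 regions 0.24) from the median of all regions, outside the range of -0.09 to 0.07 that held 95% of random sets and below all 10000 of them. Without centring, the median log2 difference was 0.0163, below the range of 0.12 to 0.28 that held 95% of uncentred random sets, at median signals of 7.72 in replicate 1 and 7.99 in replicate 2. Glycolysis genes lay at the edge of their random range, at -0.12 over 21 regions, and liver genes were above theirs at 0.50, a value that rests on 3 regions. The other 15 of the 18 lists compared lay inside their random range, among them endothelial and endocardial genes at 0.05, fibroblast genes at 0.05 and cell cycle genes at 0.05. Each side was a single library and signal values came from separate peak calls, so no replicate error stands behind these differences.

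Regions of a single library were counted against the other library's permissive set, and the count rests on that choice. In replicate 1, 119 regions, or 0.567% (0.470 to 0.678%), were overlapped by nothing in the permissive set of replicate 2, and in replicate 2 the number was 816, or 3.24% (3.03 to 3.47%). Against the other library's thresholded set the numbers were 2170 and 6566. The 119 and 816 regions had lower median signals than all regions of their library, 5.62 against 9.80 in replicate 1 and 7.50 against 10.97 in replicate 2, and 76.5% and 74.4% of them were distal. The strongest of replicate 1 were nearest to Polr3k, with a signal of 9.89, Trib2, with 8.89, and Agpat4, with 8.63. The strongest of replicate 2 lay in introns, nearest to Myo1d, with 17.8, Bmper, with 15.7, and Zfp804a, with 15.0.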

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

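The search for signal outside the sequences compared in the main text was made without a prediction. The ranked lists, whose stated inputs name no exclusion list, held entries on unplaced or unlocalised sequences of the assembly, which none of the comparisons used. There were 124 such entries in replicate 1 and 97 in replicate 2, with highest signal values of 31.3 and 31.9, and the series has no control library to set beside them. The thresholded and pseudoreplicated sets of both libraries held no entries there. No explanation of these entries was tested.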

How the results depend on the processing

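Of the 630 values obtained under alternatives, 535 kept their direction and their side of the threshold or, for values with no test, stayed within a tolerance, 37 moved beyond it, 22 passed where the main value had not, 16 no longer passed and 20 changed sign. The tolerance was a factor of 1.5 for counts (equality for the count of motifs below background), the 95% interval for overlap and correlation, the SD between the libraries for the promoter share, and 0.5 of the width of the random range for differences between the libraries, where a changed sign counted as such for values outside that range. The use of the mean, of neighbouring members counted once, of 20 shuffles and of distal regions without mitochondrial matches was chosen after seeing the data, and the other alternatives before. The excess of distal regions around cardiomyocyte genes passed under all 10 alternatives, with medians or means from 1.5 to 3.5 above random, and so did that of cardiac transcription factors, from 0.823 to 3. The excess of the MEF2 motif ranged from 5.51 to 11.4 points, of TEAD from 5.49 to 8.39 and of GATA from 2.48 to 4.68, and all passed. Unless a reason is given, the cause was not tested. Read depth is unknown, which limits any statement on regions not called, and only 2 libraries of 1 group were available, so no paired analysis was possible.

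Counts of regions follow from the set by construction. The permissive sets held 54175 regions in replicate 1, 63519 in replicate 2 and 43030 in both, unmerged entries numbered 39905, 50297 and, in the pooled set, 63136, and the pooled replicated and pseudoreplicated sets held 70085 and 72395. Overlap of replicate 1 and replicate 2 was 83.9% and 70.03% at a reciprocal overlap of 0.5, 80.5% and 79.1% for equal numbers of strongest regions, 82.7% and 69.1% in the permissive sets, and 92.6% and 75.3% at an IDR of 0.01. The Spearman coefficient was 0.862 in the permissive sets. The promoter share was 42.8% within 500 bp, 51.2% within 2 kb, 55.5% with every transcript start, 40.0% in the conservative pooled set and 23.2% in the replicated pooled set. With the other library's thresholded set as the comparison, 2170 regions of replicate 1 and 6566 of replicate 2 belonged to a single library, since that set is smaller.

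For promoters, values are points above other genes. Limiting the comparison to genes with a region within 100 kb, which by construction removes almost only genes without an accessible promoter and raises the background, gave 15.2 for cardiomyocyte genes, which no longer passed (exact adjusted p = 0.155, from 9.4e-05 to 0.155 over the alternatives), and -33.6 for endothelial and endocardial genes, which passed. In the permissive sets, cardiac transcription factors (26.2), conduction and ion channel genes (26.2, a changed sign) and lung (-37.2) passed, neural crest and Schwann (-29.9) and neuron (-22.2) no longer passed, and endothelial and endocardial (12.8) and fibroblast genes (3.92) changed sign. At an IDR of 0.01, endothelial and endocardial (-38.0) and fibroblast genes (-31.9) passed and smooth muscle and pericyte genes changed sign (-9.68). Within 500 bp, endothelial and endocardial (-25.7) and erythroid genes (-31.5) passed, and within 2 kb neural crest and Schwann genes (-30.1) no longer did. With every transcript start, cardiac transcription factors (28.4) and erythroid genes (-29.4) passed. With a library left out, values ranged from 2.10 to 4.94 for conduction and ion channel genes, a changed sign both times, and from -29.2 to -26.5 for erythroid genes, which passed without replicate 1.

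For distal regions, values are medians above random, and 5 lists passed in the 50 kb window. Conduction and ion channel genes passed in that window (1) and by the mean (0.928), and endothelial and endocardial genes in that window (1), in the permissive sets (3.5), by the mean (0.849) and without replicate 2, with 1.5 whichever library was left out. Fatty acid oxidation passed with no matching (1.5) and lung in the permissive sets (4). Pluripotency and germline genes no longer passed in the permissive sets (2.5), with no matching (1.5), by the mean (0.694), with neighbours counted once (1.5) or without replicate 2, with values from 1.5 to 2.5 when a library was left out. The sign changed for glycolysis in the 200 kb window (-0.5) and, by the mean, for smooth muscle and pericyte (-0.0076) and erythroid genes (-0.0128).

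For motifs, values are points above background, and the number of motifs below background was 0 in 100 bp windows, 2 in 400 bp windows and 0 against flanking sequence. NKX2-5 changed sign in 100 bp windows (0.701, passing), against flanking sequence (1.02, passing) and with 20 shuffles (0.127), passed as lower in 400 bp windows (-1.51), and ranged from -0.424 to 0.0127 with a library left out. TBX5 no longer passed in 100 bp windows (-0.175) or against flanking sequence (-0.256), nor did ESRR against flanking sequence (0.128). OCT changed sign in 100 bp windows (-0.0159) and against flanking sequence (-0.367), no longer passed with 20 shuffles (0.240), and ranged from 0.111 to 0.418 with a library left out, not passing without replicate 1. The neuronal E-box no longer passed in 100 bp windows (0.621) or with 20 shuffles (0.862). RUNX changed sign against flanking sequence (-0.383) and ranged from 0.249 to 0.342 with a library left out, passing without replicate 2. With a library left out, ETS ranged from 0.101 to 0.114 and passed both times, HNF4 from -0.0276 to 0.127 and the SOX10-like dimer from -0.0184 to 0.0127, each with a changed sign.

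Without centring, the log2 differences between the libraries were shifted by the median of all regions, by construction. They became 0.0163 for cardiomyocyte and 0.0837 for glycolysis genes, both with a changed sign that follows from the shift, 0.15 for cardiac transcription factors, 0.17 for conduction and ion channel, 0.19 for fatty acid oxidation, 0.25 for cell cycle, 0.26 for endothelial and endocardial, 0.26 for fibroblast, 0.0456 for smooth muscle and pericyte and 0.15 for housekeeping genes. At a reciprocal overlap of 0.5, the smooth muscle and pericyte value was 0.0388. The values of cardiac transcription factors, conduction and ion channel, fatty acid oxidation, smooth muscle and pericyte, and housekeeping genes had been negative with centring too, but inside their random ranges, and are counted above as moved. Relative to its own uncentred random range, of 0.12 to 0.28, the cardiomyocyte value was still below.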

Other observations

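All tests below were chosen after the patterns they address had been seen, with predictions written before their own values were known, except that the values for the Hox genes as a family, for single lists matched on CpG content and for motifs other than MEF2 in the comparison of the libraries had no prediction. For the Hox paralogue groups and the MEF2 motif near cardiomyocyte genes, a share that was not higher had been set as the mark against the hypothesis. Both values met that mark. Their reading was changed to undecided after the values were seen, because the differences lay within counting error. In the comparison of the libraries, the MEF2 value also met the mark against a smaller share of cardiomyocyte chromatin in replicate 2. That question was likewise called undecided only after the values were seen, for the reasons given with it.

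Hox genes, which pattern the body axis, had few accessible promoters in the newborn heart. Of 39 Hox genes, 1 had an accessible promoter in both libraries, or 2.56% (0.0649 to 13.5%), against a mean of 67.6% in random lists matched on promoter CpG content (permutation p = 0.0002, the smallest possible). The exception, named after its value was seen, was Hoxc6. Hox genes lie side by side in clusters A to D, so they are not independent and the p value overstates the evidence. Only the thresholded sets and the 5' end of each gene were used for this comparison. A hypothesis that genes of paralogue groups 1 to 5, which are active nearest the head, were accessible more often was also tested. The share was 0% in these 15 genes (0 to 21.8%) and 4.17% in the 24 genes of groups 6 to 13 (0.105 to 21.1%; Fisher's exact p = 1), and with 1 accessible gene in all the groups cannot be told apart.

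The regions near cardiomyocyte genes were also searched for the motifs. The hypothesis was that the MEF2 motif is more frequent there than at other distal regions. It was present in 6.25% of 64 distal regions within 100 kb of a cardiomyocyte gene (1.73 to 15.2%) and in 9.33% of 6217 others (Fisher's exact p = 0.519). The value near the genes was not higher, but its interval spans the other, so the shares cannot be told apart with 64 regions. No motif passed in the comparison of these sets (exact adjusted p = 1 for each of the 21).

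The strongest distal regions were searched for nuclear copies of mitochondrial DNA and for sequence present in other copies on the nuclear chromosomes. A match to the mitochondrial genome at 80% identity or more over at least 50% of the length was found for 4 of the 10. This was fewer than the 5 set beforehand as the mark of this explanation and more than the 1 set as the mark against it. The rule thus gave no verdict for the 10 as a group. The 4 matched at 95.8 to 99.7% identity, and 0.0159% of the other distal regions had a match. Mitochondrial sequence was therefore far more frequent among the strongest regions than among the others. The region near Abcb11 matched at 100% identity over 48.3% of its length and was not counted. Another chromosomal copy at 90% identity or more was found for 5 of the 10, against 0.5% of 200 other distal regions, as predicted if reads from several copies may be counted at one place. The regions near G6pd2, Nxph1 and Galc had this match and the mitochondrial one, so the explanations overlap. Those near Pak3, Hic2 and Frmd4a had no match of either kind, and no biological explanation was tested because the design holds 1 group.

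Promoter accessibility rises with CpG content, from 0.684% in the lowest of 10 equal classes of protein-coding genes to 91.0% in the highest, so the lists were compared with random lists of the same CpG classes. Cardiomyocyte genes were 45.5 points above them (75% against a central range of 17.9 to 42.9%), the joined fatty acid oxidation, glycolysis, cell cycle and housekeeping lists 25.03 points above, and the 8 joined lists that were lower lay below, at -27.7 points. All of these lay outside the central 95% of the matched lists. The joined lists were made of lists picked because they had passed on these same promoters. This favours an extreme value, so their joint result decides little. Singly, with adjustment over all 21 lists, the cardiomyocyte, fatty acid oxidation, glycolysis and housekeeping lists passed as higher. The neuron, skeletal muscle, pluripotency and germline, intestine and pancreas, and neural crest and Schwann lists passed as lower. Their permutation adjusted p values ranged from 0.0021 to 0.0350, which argues against CpG content as the whole cause for these lists. Singly, the cell cycle, immune, liver and thymus lists did not pass with matching, at 19.03, -17.6, -15.4 and -17.1 points (permutation adjusted p = 0.0731, 0.0567, 0.0641 and 0.159). Before adjustment, the cell cycle list (95.2% against 57.1 to 90.5%) still lay outside the central 95% of its matched lists. So did the immune (0% against 6.25 to 31.25%) and liver lists (0% against 5 to 30%). The thymus list, at 0% against 0 to 40%, could not have passed as lower. The immune and liver lists were also at the lowest share possible, so their p values could not have been smaller. For the immune, liver and thymus lists, not passing is therefore no evidence for CpG content as the cause. The matched lists of the cell cycle, immune, liver and thymus lists had means of 76.2, 17.6, 15.4 and 17.1%. CpG content may thus account for much of the differences from other genes, but whether for all of them was not decided. With matching, cardiac transcription factors lay at -13.2 points and erythroid genes at 0.74 points, each on the other side of the background than without it, and neither passed.

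The relatively lower signal of cardiomyocyte genes in replicate 2 was weighed against explanations from region class and from cell composition. With random sets matched on promoter or distal class, the median log2 difference of -0.19 was still below all of them, and it was -0.20 at promoters and -0.19 at distal regions, which argues against a different mix of classes. For a smaller share of cardiomyocyte chromatin in replicate 2, the prediction was a lower signal at distal regions with the MEF2 motif. It was not met, as these regions had a median log2 difference of 0.081, above the random range of 0.01 to 0.07. A value at or above the random median had been set beforehand as the mark against this explanation, and that mark was met. Regions with the GATA motif (-0.05) and the CArG box (-0.06) were below their ranges and those with the AP-1 motif (0.10) and the TEAD motif (0.0626, against an upper limit of 0.0617) above theirs. The prediction took regions with the MEF2 motif to stand for cardiomyocyte chromatin, which these data do not show. The motif was in 6.25% of distal regions near cardiomyocyte genes and in 9.33% of the others. The GATA and CArG box values go with a smaller share, the MEF2 and TEAD values do not, and that of NKX2-5 (0.0149) lay inside its range. No motif was shown here to mark cardiomyocyte chromatin. The question of a smaller share was therefore called undecided, a reading made after the values were seen. A difference in depth or in the peak calls was not tested.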
